A study of Homo sapiens with 4 samples.

How the data were processed

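The data are 4 arrays of total RNA from human B-cell precursor ALL lines grown in RPMI medium with serum. Per the labels' protocols, RNA was reverse-transcribed, amplified and biotin-labelled for Affymetrix whole-transcript arrays. The deposited log2 values come from RMA (background correction, quantile normalization and a summary per probe set) and Partek software, per the submitters' processing notes. Their versions, roles and annotation build are not given in the sources used here. The table states no scale. The log2 scale was inferred from its values, which run from 3.44 to 14.3 with means of 7.08 to 7.12 on every array. RMA gives no detection call, so that signal over background is unknown per probe set, and its quantile step removes array-wide differences in total signal before any comparison. RNA sequencing of the same lines was not used here.

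Groups follow the labels: the translocation group holds RS4;11 (replicate 1) and SEM (replicate 2), and the group without it holds NALM6 (replicate 1) and REH (replicate 2). The replicate is the cell line, with 1 array each, so that p-values measure the spread between lines, culture and array included, and any other difference between these lines enters the contrast. The labels name no batch. Of 32968 probe sets in the table, 19310 had exactly 1 gene symbol in the platform annotation, 1752 had several and 11906 had none listed. Only those with 1 symbol were named, and 19279 of them matched the RefSeq table of assembly GRCh38.p14 by Entrez ID, which updated 0 symbols. That table was used for names and for which genes neighbour each other. No coordinates are given, since the build of the array annotation is not stated. A gene with several probe sets (685 genes) was represented by the one with the highest mean, and in 0 of these genes did probe sets differ 2-fold or more in opposite directions. This left 18377 genes.

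Group differences were tested with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, without covariates, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. P-values are two-sided, except for fry's test of changes in either direction and the permutation p-values of the window scans. The latter are one-sided, for the lowest and the highest window separately. The fit had 2 residual and 1.34 prior degrees of freedom, and the median SE of a difference was 0.14 on the log2 scale. A positive difference means higher in the translocation lines. Because 2 lines against 2 cannot give an exact p below 0.333, genes were also counted whose groups were separated by at least 2-fold, with the same count for the other pairings of the lines. Line-specific genes differed from each of the other 3 lines by at least 4-fold. Of 28 gene lists, 27 had at least 3 measured members and were tested with limma's camera at a preset correlation of 0.01, with adjustment over lists. The lists came from general knowledge of B-cell leukaemia and of cell pathways, and some share members. Camera with an estimated correlation (statmod 1.5.0), camera on ranks, fry and the percentile of each list's median among 10000 random lists of like size and expression (20 expression bins) were set beside it. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

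The groups, tests, gene lists, most alternatives and the rule for named genes were fixed before the data were examined. The rule takes KMT2A and AFF1, the 12 largest separations in each direction among genes above the median of all values in both lines of the higher group, and up to 4 members with the largest differences per list with any that passed. It also takes the 4 genes highest and 2 farthest below the other lines in each line, CDKN2A, CDKN2B, MTAP, MSH6 and NR3C1 by line, and the 5 smallest p-values per direction. Members that passed adjusted over their list alone (CSPG4, SKIDA1, NHEJ1, LIN28B and SREBF2), HOXA2 and the genes of the closing observations outside this rule were chosen after their values were seen. Some genes of the rule are not analysed here. The alternatives were repeated quantile normalization, centring of arrays on their medians, the mean of a gene's probe sets, removal of dim genes (highest value below the median of all gene values), an intensity trend or robust eBayes, no moderation, all probe sets, other thresholds and leaving out each line. Protein-coding genes alone, lists without shared members and SNORD116 as 1 transcript were added after seeing the data.

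The procedure was tested on simulated data with 18377 genes, 2 lines against 2 and 200 changed genes, in 10 simulations that used the fitted variances, which is a favourable case. Limma called 4.6% of genes changed 2-fold, 66.8% at 4-fold, 82.6% at 8-fold and 94.2% at 64-fold, with 8.3 unchanged genes called per simulation. The separation count found 19.6%, 94.6%, 98% and 99.8%, with 110.6 unchanged genes per simulation. A list of 20 genes shifted by 0.5 was called in 10 of 10 simulations at the preset correlation and in 0 of 10 with an estimated one. Genes were simulated independently of each other, so that calls made through correlated members at the preset correlation were not tested. With an estimated correlation camera tests on the 2 residual degrees of freedom of the fit, so that it has little power here even where genes are independent. In the 7 lists that passed in the data, the estimated correlation ran from -0.013 (MHC class II) to 0.507 (genes high in ETV6-RUNX1 ALL). For the closing observations, the median difference in windows of 25 neighbouring expressed genes, the single window size used, was set against 1000 random gene orders for the groups (200 for single lines). In a simulated scan of 10289 genes, 20 of 20 runs of 100 genes shifted by -0.75 were found, and 0 of 20 where there was none. The case without a run was itself a random gene order, so that few finds were fixed in advance. Neighbouring genes that vary together were not simulated, and the scans of the data held other numbers of genes (9738 and 10238).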

Results

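Total RNA of 4 human B-cell precursor acute lymphoblastic leukaemia (ALL) cell lines was profiled on Affymetrix whole-transcript arrays, with 1 array per line. RS4;11 and SEM carry the translocation t(4;11), which joins KMT2A (MLL), the gene of a histone H3 lysine methyltransferase, to AFF1, the gene of a transcription elongation factor. They are called the translocation lines. NALM6 and REH are precursor B-cell ALL lines without this translocation and form the comparison group. The comparison asked which transcripts differ between leukaemia lines with and without a rearranged MLL gene. Expression values are log2 values processed by the submitters, and the median over all probe sets lay between 6.40 (NALM6) and 6.46 (RS4;11 and SEM). Values near 5 lie close to the 25th percentile of each array (4.97 to 5.02), so that folds against them are a compressed measure. Group levels are means ± SD over 2 lines, and the number of arrays limits their precision.

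KMT2A itself was at 11.12 in RS4;11, 10.61 in SEM, 10.72 in NALM6 and 11.01 in REH. AFF1 lay at 11.69, 10.89, 11.22 and 11.30 in the same order. The difference between the groups was 0.00 for KMT2A (SE 0.24, adjusted p = 1) and 0.03 for AFF1 (SE 0.32, adjusted p = 0.985), and both signs turned after repeated quantile normalization (-0.04 and -0.01), and that of KMT2A with the mean over its probe sets (-0.10). The positions of probe sets relative to the breakpoints were not used here, so that these levels do not separate fusion from normal transcripts and check nothing about the labels.

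Among 18377 genes, 4 passed limma's threshold, S100A10 and MEIS1 upward and MME and DTX1 downward in the translocation lines. S100A10, the annexin A2 ligand, rose from 4.99 ± 0.12 in the lines without the translocation to 12.57 ± 0.07 in the translocation lines, a 190.3-fold difference (log2 difference 7.57, SE 0.11, adjusted p = 0.0212). MEIS1, a homeobox cofactor of HOX proteins, rose from 4.87 ± 0.07 to 11.25 ± 0.07, 82.9-fold (difference 6.37, SE 0.10, adjusted p = 0.0212). MME, which encodes the surface peptidase CD10, was 136-fold lower, at 5.44 ± 0.14 against 12.52 ± 0.06 (SE 0.12, adjusted p = 0.0212). DTX1, a Notch pathway ubiquitin ligase, was 42.2-fold lower, at 5.06 ± 0.01 against 10.46 ± 0.16 (SE 0.12, adjusted p = 0.0431). Each of the 4 was ordered the same way in every pair of a translocation line and another line. This follows from the large differences and small spreads by which they passed.

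Several further genes stood far apart between the groups without passing the adjustment. PTPRR, a receptor tyrosine phosphatase, was at 11.33 ± 0.21 in the translocation lines and 5.01 ± 0.17 in the others, and DST, a cytoskeletal linker, at 7.92 ± 0.01 and 4.97 ± 0.03 (adjusted p = 0.0513 for both). CD44, a hyaluronan receptor, was at 11.04 ± 0.05 and 6.18 ± 0.27 (adjusted p = 0.0587). The same adjusted p applied to PRSS12, CD96, LAMP5, GALC and HTR1F, whose log2 differences were 6.72, 6.57, 6.54, 5.08 and 5.13. The chemokine gene CCL28 differed by 5.24 (adjusted p = 0.0614), and CPNE8 and TES by 6.16 and 5.52 (adjusted p = 0.168 for both). In the other direction, TCF4, a transcription factor of lymphoid and plasmacytoid dendritic cells, was at 5.90 ± 0.27 against 11.83 ± 0.08, CYBB, an NADPH oxidase subunit, at 4.84 ± 0.26 against 10.77 ± 0.13, and RGS9 at 5.03 ± 0.10 against 8.64 ± 0.08 (adjusted p = 0.0513 for each). The differences were -5.11 for STK32B, -5.43 for the histone demethylase gene KDM5B, -5.26 for BEST3, -4.99 for AKAP12, -5.34 for RUBCNL, -4.37 for the calcium channel gene ITPR3 and -4.86 for CD200. Their adjusted p-values lay between 0.0721 for STK32B and 0.313 for RUBCNL.

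**Figure D1:**
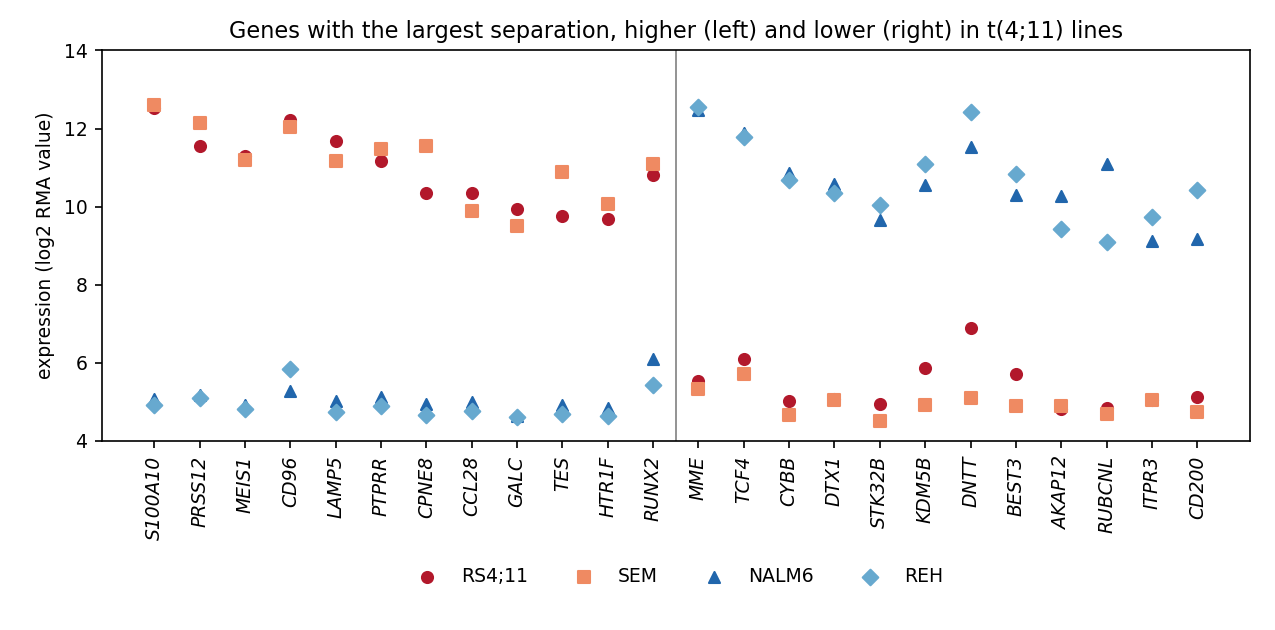
Expression (log2 RMA value, vertical axis) of the 12 genes with the largest separation in each direction, with 1 point per cell line. Both translocation lines lie above both other lines on the left and under them on the right, with S100A10 at 12.52 (RS4;11) and 12.61 (SEM) against 5.08 (NALM6) and 4.91 (REH).

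At an adjusted p under 0.1 there were 42 genes, 28 higher and 14 lower in the translocation lines, and at an unadjusted p under 0.05 there were 1725 (845 higher, 880 lower). Leaving out RS4;11, SEM, NALM6 or REH left 1 residual degree of freedom, and no gene then passed limma's threshold. The differences themselves stayed as large, at 7.49 to 7.66 for S100A10, 6.32 to 6.42 for MEIS1, -7.18 to -6.98 for MME and -5.51 to -5.28 for DTX1. Genes that pass have a small spread within the groups, so that leaving out a line could move these differences only little. The smallest adjusted p-values were 0.152, 0.224, 0.115 and 0.14, with 1559, 1254, 2585 and 1859 genes at an unadjusted p under 0.05. The count of 4 also depended on scaling and filtering, with 28 genes (19 higher, 9 lower) after each array was centred on its median, 17 (12 higher, 5 lower) without dim genes and 9 after repeated quantile normalization, the 4 genes included each time. An exact permutation test of a single gene cannot go below p = 0.333 in this design.

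Genes were also counted without a test. In 177 genes the lower translocation line exceeded the higher of the other lines by at least 2-fold, and in 161 genes the order was the opposite, which makes 338. The other pairings of the 4 lines gave 113 genes (RS4;11 and NALM6 against SEM and REH) and 107 (RS4;11 and REH against SEM and NALM6). At 4-fold the counts were 123, 32 and 23. The groups did not overlap in 7864 genes (42.8%), against 33.3% by chance. Without RS4;11, SEM, NALM6 or REH the separated genes numbered 542, 342, 492 and 444 (higher) and 373, 342, 681 and 430 (lower), since fewer lines then had to be parted.

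Genes known to be high in MLL-rearranged ALL shifted upward as a list, with a median log2 difference of 0.77 over 35 measured members (limma camera, adjusted p = 1.53e-08, and adjusted p = 0.59 with an estimated correlation). Over all genes 1 member rose, MEIS1. Adjusted over the list alone, 10 rose and 2 fell. RUNX2, a Runt transcription factor, was at 10.95 ± 0.21 against 5.76 ± 0.47 (adjusted p = 0.0984 over all genes), and PROM1, a stem cell surface marker also known as CD133, at 12.46 ± 0.23 against 6.73 ± 1.96 (adjusted p = 0.364). CSPG4, the NG2 proteoglycan used as a diagnostic marker of MLL-rearranged ALL, was at 7.97 ± 0.48 against 5.28 ± 0.64. TCF4 and SKIDA1 were the members that fell over the list alone, against the direction of the list.

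Genes known to be low in MLL-rearranged ALL shifted downward, with a median difference of -1.69 over 16 members (adjusted p = 6.43e-06, and adjusted p = 0.712 with an estimated correlation). MME alone fell over all genes. Adjusted over the list alone, 4 fell, namely MME, DNTT, ALOX5 and BLNK. DNTT, the terminal transferase of V(D)J joining, was at 5.99 ± 1.26 against 11.98 ± 0.63, and BLNK, the adaptor downstream of the pre-B receptor, at 6.25 ± 1.27 against 11.20 ± 0.76. The lipoxygenase gene ALOX5 was at 5.83 ± 0.90 against 10.62 ± 0.57. SEM contributed most of this shift: its own list median lay -2.46 from the mean of the other lines. The median difference was -0.51 without SEM, -2.96 without RS4;11, -1.86 without NALM6 and -1.80 without REH. That of RS4;11 alone lay at 0.08, but against a mean that includes the low SEM. The median levels of the list were 9.27 in RS4;11, 6.50 in SEM, 10.78 in NALM6 and 11.02 in REH, so that RS4;11 also lay below NALM6 and REH. Over the scalings and filters camera's adjusted p was at most 3.68e-05.

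The pre-B receptor and V(D)J recombination list, which shares 6 of its 16 measured members with other lists that passed camera, shifted by -0.75 (adjusted p = 0.0432, and adjusted p = 0.845 with an estimated correlation). No member passed over all genes, and adjusted over the list alone 3 fell (DNTT, BLNK and LIG4) and 1 rose (NHEJ1). The last 2 encode partners in DNA end joining, LIG4 at 7.30 ± 0.14 against 10.52 ± 0.49 and NHEJ1 at 10.15 ± 0.01 against 8.95 ± 0.02. RAG2, a recombinase subunit, was at 10.94 in RS4;11 but 6.31 in SEM, with 11.86 in NALM6 and 13.43 in REH. The shift no longer passed without SEM (-0.13, adjusted p = 0.118), NALM6 (-0.89, 0.355) or REH (-1.07, 0.06), after repeated quantile normalization (0.105), without dim genes (0.0529), with robust eBayes (0.174) or on ranks (0.0865), and it was -1.48 without RS4;11 (5.81e-05). After the shared members were removed, a step chosen after the data were seen, it was -0.28 (adjusted p = 0.733).

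Cholesterol synthesis genes shifted upward by a median of 0.52 over 17 members (adjusted p = 3.27e-06, and adjusted p = 0.67 with an estimated correlation). No member passed over all genes, 10 were higher at an unadjusted p under 0.05, and 2 rose adjusted over the list alone. These were HMGCS1, the synthase ahead of HMG-CoA reductase, at 11.09 ± 0.22 against 9.59 ± 0.03, and SREBF2, the transcription factor that controls the pathway, at 10.70 ± 0.08 against 9.82 ± 0.05. The squalene epoxidase gene SQLE was at 11.45 ± 0.36 against 10.25 ± 0.22, STARD4 at 9.40 ± 0.41 against 8.32 ± 0.29, and MVK at 7.77 ± 0.29 against 6.70 ± 0.18. Without each of the lines in turn the median stayed above 0, from 0.37 without NALM6 to 0.73 without REH. Relative to the mean of the other lines, the list median was 0.34 in RS4;11, 0.38 in SEM, -0.54 in NALM6 and -0.16 in REH.

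Antigen presentation lists shifted downward by smaller amounts. MHC class I presentation had a median difference of -0.43 over 10 members (adjusted p = 0.0151, and adjusted p = 0.67 with an estimated correlation), and no member passed over all genes or adjusted over the list alone. The difference of the peptide transporter gene TAP1 was -1.39 (SE 0.50), and the immunoproteasome gene PSMB9 was at 9.38 ± 0.24 against 10.18 ± 0.06. MHC class II had a median difference of -0.25 over 14 members (adjusted p = 0.0261, and adjusted p = 0.67 with an estimated correlation). Its only member to pass adjusted over the list alone went the other way, HLA-DQB1, with a difference of 1.94 (SE 0.10, adjusted p = 0.092 over all genes), while HLA-DPB1 was at 11.84 ± 0.14 against 12.57 ± 0.21. The class I shift did not pass without SEM (-0.40, adjusted p = 0.0566) or NALM6 (-0.30, 0.25), and the class II shift not without SEM (-0.17, 0.0875), NALM6 (-0.27, 0.25), REH (-0.22, 0.0581) or dim genes (-0.25, 0.0843). Without RS4;11 the class II shift was -0.41 (adjusted p = 0.0174). With robust eBayes the adjusted p was 0.111 for class I and 0.723 for class II, and with an intensity trend class II had 0.252.

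Genes known to be high in ALL with the ETV6-RUNX1 fusion, which REH carries, shifted by -0.85 over 20 members (adjusted p = 0.00152, and adjusted p = 0.845 with an estimated correlation). No member passed over all genes or adjusted over the list alone. REH carried this shift: its list median lay 1.43 above the mean of the other lines, at the 100th percentile of 10000 random lists matched on expression, and the shift was -0.01 without REH (adjusted p = 0.773) and -1.34 without NALM6 (9.97e-12). With robust eBayes the list did not pass (adjusted p = 0.053). IGF2BP1, an RNA-binding protein gene, was at 10.69 in REH and between 4.76 and 4.83 in the other lines, and PTPRK at 11.56 against at most 7.47. Genes known to be high in DUX4-rearranged ALL, the rearrangement of NALM6, had a median difference of -2.18 over 10 members and did not pass (adjusted p = 0.0924, and adjusted p = 0.845 with an estimated correlation). In NALM6 alone their median lay 3.44 above the mean of the other lines, also at the 100th percentile, with PTPRM at 10.19 and at most 6.56 elsewhere. The shift was -3.75 without REH (adjusted p = 2.73e-05), -0.57 without NALM6 (0.31) and -1.96 without RS4;11 (0.73), and with centred arrays it passed (-2.16, adjusted p = 0.0324).

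The other lists did not pass camera. The haematopoietic stem cell list came nearest, with a median difference of 0.04 (adjusted p = 0.0673), 1 member that rose over all genes (MEIS1) and 2 that rose adjusted over the list alone (MEIS1 and LIN28B), and it passed with robust eBayes (adjusted p = 8.44e-11), with an intensity trend (6.46e-07), with centred arrays (0.07, 0.0352), without RS4;11 (0.08, 0.0218) and without REH (0.14, 0.00414), but not without SEM (0.03, 0.118) or NALM6 (0.03, 0.675), after repeated quantile normalization (0.0046, 0.081), with the mean of a gene's probe sets (0.04, 0.0725) or on ranks (0.282). With an estimated correlation its adjusted p was 0.712. Removal of dim genes left 6 of its 21 members (2.28, adjusted p = 0.000196), a subset that the filter picks partly by the difference itself. The receptor tyrosine kinase gene FLT3, on the same list, was at 12.08 ± 1.05 against 9.40 ± 1.33. Interferon-stimulated genes had a median of -0.17 (adjusted p = 0.105), with IFIT3 the 1 member that fell adjusted over the list alone, at 5.72 ± 0.03 against 7.09 ± 0.14, and they passed without NALM6 (-0.42, adjusted p = 0.00119), while without REH the median was 0.03 (0.868). MYC and translation targets had a median of 0.16 (adjusted p = 0.202) and passed without NALM6 (0.31, adjusted p = 0.000479), while the median was 0.03 without REH (0.773), 0.10 without SEM (0.643) and 0.25 without RS4;11 (0.209). The KMT2A complex and its elongation partners had a median of -0.02 (adjusted p = 0.297) and early B lineage factors and antigens of -0.16 (adjusted p = 0.71). Both passed without RS4;11 (-0.15, adjusted p = 0.0292, and -0.28, adjusted p = 0.0144), and both signs turned without SEM (0.12, 0.953, and 0.06, 0.817). With an estimated correlation and all 4 lines, the adjusted p was 0.845 for interferon-stimulated genes, 0.858 for both MYC targets and the KMT2A complex, and 0.903 for early B lineage.

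Adhesion and migration genes had a median of 0.09 (adjusted p = 0.798), with CD44 the 1 member that rose adjusted over the list alone. In the BCL2 family list (0.04, adjusted p = 0.918) HRK, a pro-apoptotic BH3-only gene, fell adjusted over the list alone, at 7.82 ± 0.10 against 8.83 ± 0.04. None of the remaining lists had a member that passed adjusted over the list alone. Among other cell types the medians were 0.05 for mature B cell (adjusted p = 0.918), 0.04 for myeloid (0.751), 0.04 for T and NK cell (0.674), -0.01 for erythroid and megakaryocyte (0.798) and 0.05 for stromal and epithelial genes (0.362). Most members of these lists were dim. Without dim genes 11 of 30 myeloid members were left (median 0.61, adjusted p = 0.383), 6 of 24 of T and NK cell (0.54, 0.236), 8 of 22 of mature B cell (0.09, 0.876), 5 of 19 of stromal and epithelial genes (0.10, 0.292) and 1 of 18 of erythroid and megakaryocyte, too few for a value, while 10 of 15 of the BCL2 family had a median of 0.21 (0.793). For cell state lists they were -0.03 for proliferation (adjusted p = 0.733), -0.02 for glycolysis (0.976), -0.06 for p53 targets (0.652) and -0.15 for the unfolded protein response and stress (0.39). Without RS4;11 the p53 median was -0.12 (0.517), without REH it was -0.10 (0.773), and without NALM6 the stress median was -0.01 (0.811). Genes recurrently deleted in B-ALL with mismatch repair genes had 0.01 (adjusted p = 0.739), reference genes -0.04 (0.674) and HOX genes outside the HOXA cluster -0.01 (0.733). The sign of the median turned after centring for the KMT2A complex, erythroid and megakaryocyte, glycolysis and other HOX lists, and after repeated quantile normalization for the BCL2 family and recurrently deleted lists. Camera's direction opposed both median and mean for the mature B cell, BCL2 family, recurrently deleted and glycolysis lists. Probe sets with several gene symbols were not used. Of the HOXA list 1 of 11 genes had a probe set with exactly 1 symbol, too few for a test. This gene, HOXA2, which lies in a run of neighbouring genes lower in the translocation lines, was at 7.72 in RS4;11, 7.30 in SEM, 5.32 in NALM6 and 8.19 in REH.

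**Figure D2:**
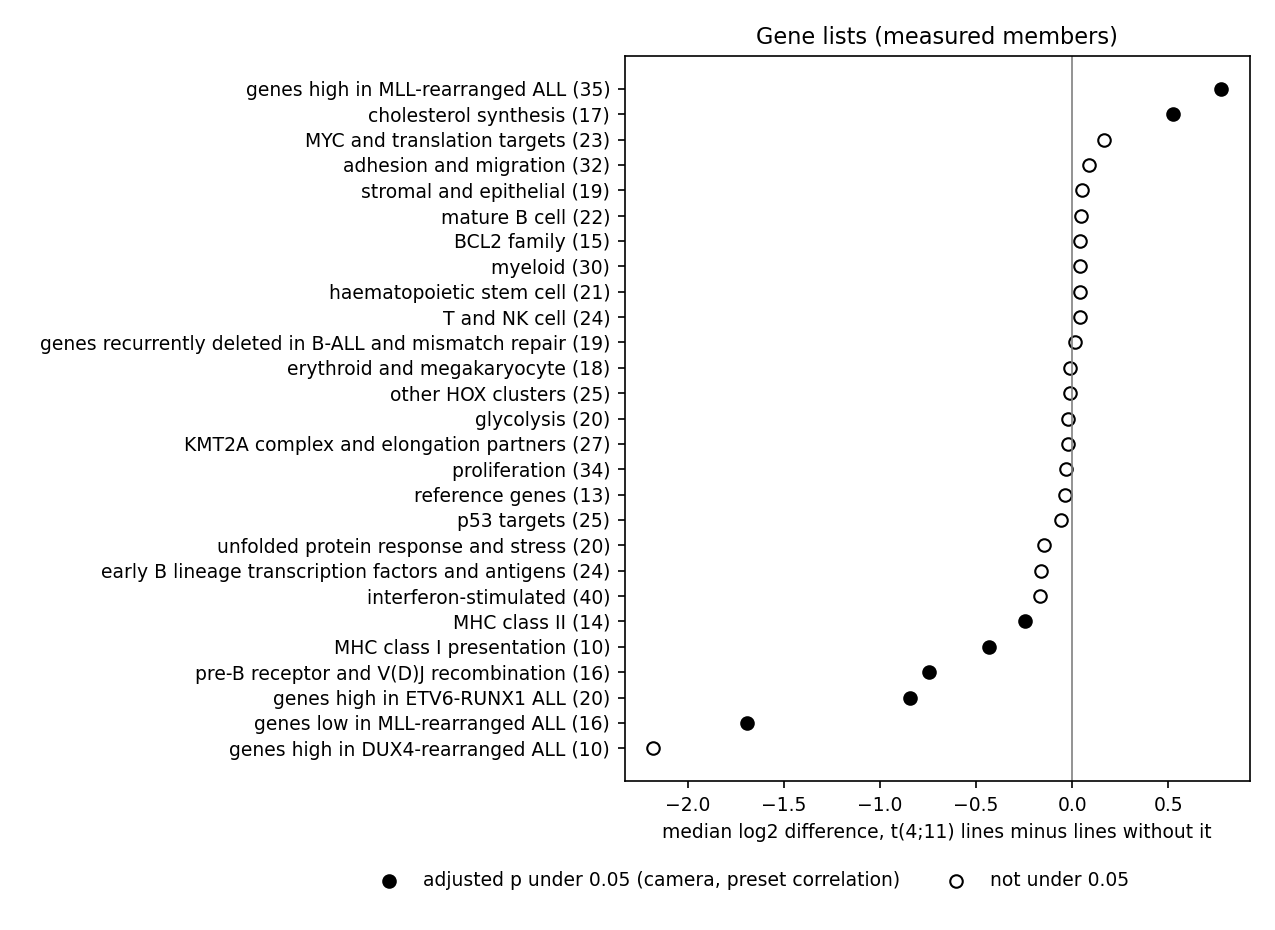
Median log2 difference (translocation lines minus lines without it, horizontal axis) of each of 27 gene lists, with the number of measured members in brackets. Filled points mark the 7 lists with an adjusted p under 0.05 by camera with a preset correlation, 2 above and 5 below 0, and open points the others, of which 6 lists change sides of 0 under another scaling.

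With an estimated correlation 0 of the 27 lists passed camera, and 1 had an unadjusted p under 0.05. This form tests on the 2 residual degrees of freedom and called 0 of 10 shifted lists in the simulated data. Its lack of calls therefore does not decide whether the lists shifted. By fry 0 lists passed for a shift in 1 direction, with 5 at an unadjusted p under 0.05, and 13 passed for changes in either direction. The 13 included the reference genes (fry, either direction, adjusted p = 0.0111), so that this test does not set the other lists apart from them. Camera on ranks called 6 lists. The same camera test with a preset correlation called 3 and 2 lists in the other pairings of the lines.

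As whole profiles, the translocation lines were the most alike. The SD of the log2 difference over genes was 0.626 between RS4;11 and SEM and 0.770 between NALM6 and REH, and it ranged from 0.745 (RS4;11 and NALM6) to 0.868 (SEM and REH) in the 4 pairs across the groups. The mean was 0.808 across groups and 0.698 within them. RS4;11 and SEM differed 2-fold or more in 1102 genes, NALM6 and REH in 1584, and the pairs across groups in 1441 to 2056. RS4;11 was thus closer to NALM6 than NALM6 was to REH.

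Genes that set 1 line apart from the other 3 by at least 4-fold were most frequent in REH (139 higher, 88 lower), followed by SEM (127 and 38), NALM6 (78 and 84) and RS4;11 (30 and 45). With 1 array per line these counts have no replicate check. In RS4;11, GTSF1, a germ cell gene of the piRNA pathway, was at 11.99 and at most 4.79 elsewhere, the prolactin gene PRL at 11.89, F13A1 at 10.18 and ADGRG7 at 9.65, while SNORD116-15 and SNORD116-14 were at 4.70 and 4.50 against at least 12.58 and 11.48, both from a cluster of near-identical copies that probes need not tell apart. SEM had MED12L at 10.75, NETO2 at 11.25, PLXDC2 at 11.48 and EMP1 at 11.01, each at most 5.40 elsewhere, and low values of CD38 (6.35) and IGHV5-78 (6.46). In NALM6 the receptor tyrosine kinase gene PDGFRA was at 10.76 and at most 4.75 elsewhere, with STAP1 at 12.22, ANKRD30B at 10.93 and PTGDR at 10.15, and low SLC35A4 (5.42) and SYPL1 (5.46). REH had IGSF10 at 11.19, PCLO at 11.28, OVCH2 at 11.50 and NETO1 at 10.71, and low BCAT1, a branched-chain transaminase gene, at 5.23 and KCNQ5 at 5.01. The mismatch repair gene MSH6 ranged from 10.23 (NALM6) to 11.33 (REH), and the glucocorticoid receptor gene NR3C1 from 9.77 (NALM6) to 11.26 (RS4;11). CDKN2A, a cell cycle inhibitor locus, and its neighbour MTAP were at 9.35 and 9.29 in SEM and between 4.60 and 4.90 in the other lines, and CDKN2B lay between 4.70 and 4.93 in all 4.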

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

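The alternatives that use protein-coding genes alone, leave out shared list members or count SNORD116 as 1 transcript were chosen after seeing the data, and all others were planned. The count of 4 genes past limma's threshold became 9 after repeated quantile normalization, 28 with arrays centred on their medians, 17 without dim genes, 9 with protein-coding genes alone, 12 over all probe sets, 42 at an adjusted p under 0.1 and 0 without moderation (1424 genes at an unadjusted p under 0.05, against 1725 with limma). The 4 genes kept their calls in these settings except without moderation, and 3 of them with an intensity trend (DTX1 adjusted p = 0.0518). The higher share was 50% as reported, 67.9% (19 of 28) after centring, 70.6% (12 of 17) without dim genes and 44.4% after quantile normalization. Leaving out each line in turn gave 0 genes (1254 to 2585 at an unadjusted p under 0.05), with 1 residual degree of freedom and the lone line of a group assumed to vary like the other group. Separated genes then numbered 342 to 542 (higher) and 342 to 681 (lower), since fewer lines had to be parted. With all 4 lines, genes separated by 4-fold numbered 74 (higher) and 49 (lower). The 7 lists became 4 with robust eBayes (both MHC lists, pre-B and ETV6-RUNX1 no longer passed, and the stem cell list did), 0 with an estimated correlation (1 at an unadjusted p under 0.05), 0 by fry (5 at an unadjusted p under 0.05), and 4 (without SEM) to 10 (without RS4;11) when a line was left out. At 2-fold the line-specific counts were 130 higher and 123 lower for RS4;11, 301 and 129 for SEM, 219 and 214 for NALM6 and 402 and 229 for REH. Scaling moved the median difference of all genes to between -0.0167 and 0.0376. No paired analysis was possible because the replicate numbers, given in order of the arrays, tie no line of one group to a line of the other.

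Signs turned only in results that had not passed, and the cause was not tested. Centring turned the medians of the other HOX clusters (0.0103), KMT2A complex (0.0045), erythroid and megakaryocyte (0.0126) and glycolysis (0.0044) lists, and quantile normalization those of the BCL2 family (-0.0035) and recurrently deleted (-0.0078) lists and the differences of AFF1 (-0.0106) and KMT2A (-0.0394). The mean over probe sets turned KMT2A to -0.10. Without dim genes the other HOX and the erythroid and megakaryocyte lists had under 3 members left and gave no value.

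When each line was left out in turn, list medians turned sign within these ranges: other HOX clusters -0.0345 to 0.025, KMT2A complex -0.1533 to 0.1188, early B lineage -0.2832 to 0.0569, mature B cell -0.0621 to 0.0961, myeloid -0.0227 to 0.0999, erythroid and megakaryocyte -0.0674 to 0.0163, interferon-stimulated -0.4199 to 0.0327, adhesion and migration -0.0459 to 0.1321, BCL2 family -0.0055 to 0.0639, proliferation -0.066 to 9e-04, glycolysis -0.1194 to 0.1711 and recurrently deleted -0.209 to 0.0665. The same held for the differences of KMT2A (-0.25 to 0.25), AFF1 (-0.37 to 0.43), MSH6 (-0.37 to 0.73), IGF2BP1 (-5.89 to 0.0213) and PTPRK (-4.72 to 1.18), and for these further list members taken by the rule for named genes: AFF3 (-1.99 to 0.74), ANPEP (-0.14 to 5.31), BCL6 (-0.65 to 2.79), CCNE1 (-1.26 to 0.17), CD86 (-0.0206 to 3.43), CLEC12A (-4.98 to 0.0921), ENO2 (-3.46 to 0.18), EPOR (-0.91 to 0.13), HOXB9 (-0.45 to 0.0266), HOXC9 (-0.51 to 0.10), IKZF3 (-4.22 to 0.59), MPO (-2.79 to 0.0394), NLRC5 (-1.92 to 0.29) and TIGAR (-0.10 to 2.27). Medians of these other lists that had not passed moved by over 1.5 times without turning: p53 targets (-0.1236 to -0.0531), unfolded protein response and stress (-0.1195 to -0.0109), MYC and translation targets (0.0345 to 0.3059), stem cell (0.0324 to 0.1398), DUX4-rearranged (-3.753 to -0.5739), T and NK cell (0.0162 to 0.0632), stromal and epithelial (0.0327 to 0.0739) and reference genes (-0.0416 to -0.0141). With 1 array in a group, such a value follows the remaining line. Over 2 scalings, the mean of probe sets and 2 forms of eBayes, named genes kept direction and side of the threshold in 617 comparisons, with 19 newly past it, 1 no longer past it and 3 turned. For lists, over 2 scalings, the mean of probe sets and the removal of dim genes, these numbers were 94, 3, 3 and 6.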

Other observations

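The genes of the first 2 paragraphs, the use of protein-coding genes alone with the tests on their run, the count of SNORD116 as 1 transcript, the test of separated genes after repeated normalization, the test of random gene orders and the test of shared SNORD116 probes were chosen after the results were seen.

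Further genes were separated between the groups. GREM1, a secreted antagonist of bone morphogenetic proteins (BMPs), was at 9.98 ± 0.39 in the translocation lines and 5.42 ± 0.12 in the lines without it (n = 2 each), and NOG, another BMP antagonist, at 10.25 ± 0.14 against 6.79 ± 0.81. TWIST1, a basic helix-loop-helix transcription factor, was at 9.84 ± 0.57 against 5.82 ± 0.15, the phospholipase gene PLA2G4A at 7.80 ± 0.18 against 4.61 ± 0.00, and SNX10, a sorting nexin gene, at 9.13 ± 0.22 against 4.84 ± 0.09. On the other side, SOCS2, an inhibitor of cytokine signalling, was at 6.46 ± 0.86 against 10.17 ± 0.07, TNFAIP3, an inhibitor of NF-kappaB signalling, at 7.13 ± 1.03 against 11.16 ± 1.21, and the surface antigen gene CD52 at 7.84 ± 0.20 against 10.86 ± 0.43. MAML2, a Notch coactivator, was at 6.63 ± 0.27 against 9.46 ± 0.44. None of these passed limma's threshold, with adjusted p-values from 0.0587 (SNX10) to 0.41 (TNFAIP3).

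Beside CDKN2A and MTAP, further genes near them were high in SEM alone. HACD4 was at 10.35, KLHL9 at 10.01 and FOCAD at 7.72 in SEM, and all 3 lay between 4.57 and 4.86 in RS4;11, NALM6 and REH. Others in between, such as IFNB1 and IFNE, were between 4.15 and 4.56 in all 4 lines, and PLAA, farther along, was between 9.73 and 10.10 in all 4. Gene copies were not measured, so that these values do not say whether the 3 lines lack the genes or do not transcribe them.

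The separated genes numbered 338 between the translocation lines and the others, against at most 113 in another pairing, and limma called 4 genes against 0 in both others (467 and 528 at an unadjusted p under 0.05). The real pairing was the 1 of 3 with as many genes in both counts, and 3 pairings are too few for a share under 0.05. An array-wide scaling difference was not tested by repeated quantile normalization (338 and at most 111), since it moved the difference of a gene by a median of only 0.0308 in values normalized this way before. The translocation and any other trait that RS4;11 and SEM share stay open, untested.

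In the scan of neighbouring protein-coding genes (9738 expressed genes, windows of 25), the lowest median difference was -0.9852, from ZNF12 to NUP42, within a longer run of low windows from PDGFA to ZNF117 with 159 genes, in which HOXA2 lies. The highest window, from PARP3 to PRKCD, was at 0.5252 and also beyond most of the 1000 random gene orders (permutation p = 0.015). For the low run a random gene order is argued against, since the lowest window in 1000 such orders was -0.7018 (permutation p = 0.001, the smallest they can give). Random orders do not mimic neighbours that vary together. A run carried by 1 line is argued against by -0.7025 in the weakest of the 4 pairs of lines. The run median was -0.6797 and still -0.5288 without the 40 genes lower by 1 or more, so that these alone did not carry it. By the bound set first, a few genes with large changes stay open, since 68.0% of window genes were lower in both translocation lines, under 75%. In the run 106 of 159 genes (66.7%) were, against 23.0% of all, but the run was picked by the same difference. Repeated quantile normalization (-0.9922) moved little and does not test scaling. The median difference over all expressed genes was 0.0084, so that these values held no common shift of the run's size. RMA's quantile step holds this median near 0, so that it does not test scaling before that step. A run in any pairing stays open, as the other 2 pairings (farthest from 0 at -0.5754) are too few. Every single-line scan also held a lowest window beyond 200 random orders (permutation p = 0.005 in each, the smallest they can give), and these lay outside this run, in RS4;11 from TNFRSF10B to INTS9 and in SEM from NHLRC3 to ZC3H13, whereas the highest windows of NALM6 (TARP to PPIA, 0.646, p = 0.005) and REH (RNF216 to SNX13, 0.733, p = 0.01) lay in it. A candidate explanation is a copy number of the region that differs between the lines, which was not measured.

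In RS4;11 small nucleolar RNAs of the SNORD116 cluster, an imprinted gene cluster, were low. Of 20 probe sets, 14 lay above the median of all gene values in each of the other 3 lines. The median of these 14 was 5.38 in RS4;11 against 9.03 (SEM), 9.03 (NALM6) and 9.48 (REH). SNORD116 copies set the lowest window of all expressed transcripts, at -1.2189 against -0.7453 in 1000 random orders (permutation p = 0.001) and -1.253 after repeated quantile normalization. Of the window's 25 transcripts, however, 16 were SNORD116 copies, 48.0% were lower in both translocation lines, and the weakest pair was at 0.0189. With SNORD116 counted as 1 transcript no window that holds it lay below 0.0137. Few transcripts and RS4;11 alone thus carry the low window, with chance order open. Repeated normalization moved little and does not test scaling. The median difference over all expressed transcripts was 0.0069, so that these values held no common shift of the window's size. RMA's quantile step holds this median near 0 as well, so that it does not test scaling before that step. Poor recovery of small RNAs is argued against by 125 other snoRNA probe sets, at a median of 0.101 relative to the other lines. Near-identical copies read by the same probes stay open: of the 14 probe sets 0 lay within 1 of the other lines and all 14 were low, so that they may amount to few independent measurements. The 14 were picked by their levels in the other lines alone, which favours low values in RS4;11, and the dimmer probe sets were not part of this test. Loss of the neighbouring transcripts cannot be told apart from a loss of SNORD116 alone. Of 22 other transcripts measured from SNRPN to UBE3A, SNRPN itself not among them, only PWAR6 and UBE3A were expressed. They differed, with PWAR6 at -1.67 and UBE3A at 0.08 relative to the other lines (median -0.797). No biological explanation was tested.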
